A study of Caenorhabditis elegans with 2 samples.

How the data were processed

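Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole L2 larvae of Caenorhabditis elegans strain OP178, males and females pooled, with chromatin broken by sonication. Per the labels, the strain carries an integrated transgene, wgIs178, that expresses the transcription factor SKN-1 with a GFP-FLAG tag at its C terminus, and the antibody field names skn-1. The free-text description of both samples instead names PHA-4, a forkhead factor. The labels therefore disagree on the protein, and the binding words and gene loci of both were tested in the same way. There is 1 group of 2 libraries, given in the labels as biological replicates 1 and 2, and there is no second condition. The numbers come from the description of each sample.

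The data are 8 peak lists: replicate 1, replicate 2, both replicates pooled, and an optimal list from the irreproducible discovery rate (IDR) procedure, each in builds ce10 and ce11. The replicate and pooled lists are relaxed lists, deposited as peaks and background for that procedure. Per the file headers in the deposited readmes, each relaxed list derives from the alignments of its own library or libraries and from a further file that is the same for both replicates, and the optimal list derives from the relaxed ones. The deposited control-normalized tracks derive from that same file, so it is taken to be the control, and the deposited signals to have been computed with it. The data of the control experiment named in the labels were not used here. The aligner, peak caller, filters and IDR cutoff are not given in the sources used here. Each deposited peak carries a signal value, the caller's enrichment on a scale of its own list. It was used to rank and describe peaks within a list. Across lists it was used only to correlate the replicates, to give the scale of each replicate's list and to compare the builds at equal rank. Each deposited peak also carries a −log10 q value. In the ce11 optimal list the largest q was 0.00531. In the relaxed lists q reached 0.960, so that most of their peaks are background by design. Read depth is not given in the peak lists and is unknown here. Intervals on shares of peaks therefore cover the counting of peaks only.

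All analyses of genes and sequence used the ce11 lists with the WBcel235 genome, whose chromosome ends no peak passed, and Ensembl release 115. The ce10 lists were compared by number, width, signal and replicate overlap, and no coordinates were converted. All 872 rows of the ce11 optimal list were identical to rows of the pooled list and were its 872 strongest peaks. The 870 summits on nuclear chromosomes were analysed for location, words and genes; 2 mitochondrial peaks were left out of those analyses. Coordinates are 1-based.

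Replicate overlap was the number of the 872 strongest peaks of replicate 1 overlapped by 1 bp or more by the 872 strongest of replicate 2, against 1000 random placements within chromosomes (one-sided permutation test). Signals of peaks matched to an optimal peak were correlated on a log2 scale with 100000 permutations. A promoter was the stretch from 1000 bp upstream to 200 bp downstream of an annotated 5' end of a protein-coding gene. Summits were assigned in the order promoter, 5' UTR, coding exon, 3' UTR, intron, other gene, intergenic, and compared with 1000 random placements (two-sided permutation test). Chromosome shares were set against length by an exact binomial test. Words were counted on both strands within 100 bp of each summit and in flank windows of the same width 500 bp to each side, over 300 bp from any optimal summit, by two-sided Fisher's exact tests over 7 words. For other sets of peaks the flank windows were cleared of that set's own summits only. All words of 7 bases were tested in the same way. Gene lists, 31 in number, were tested by two-sided Fisher's exact tests of members with a summit in a promoter against all 19973 nuclear protein-coding genes. For loci, summits within 20 kb of the gene were compared with 1000 random windows of the chromosome (one-sided permutation test). Adjusted p values are Benjamini-Hochberg values within each family, with a threshold of 0.05, and intervals are exact 95% intervals. Python 3.11, numpy 2.4.6 and scipy 1.17.1 were used. The smallest p is 0.001 for the one-sided permutation tests and 0.002 for the two-sided ones.

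Tests, gene lists, words and most alternatives were fixed before the data were examined. Genes are named by a rule fixed then too: genes with a promoter at one of the 20 strongest optimal peaks; skn-1, pha-4, gcs-1, gst-4, wdr-23, med-1 and med-2; the 4 members with the strongest peak of each list that passed; and the strongest 2 of each other list that is not a gene family. A summit between divergent genes counts for both. In the heat shock list 3 names matched no gene. The alternatives tried were stronger peaks only, each replicate's own list, other overlap rules, promoter windows, word windows, backgrounds and words, circular shifts of the summits, and the ce10 lists. Others, chosen after seeing the data, were optimal peaks among the strongest of both replicates, full-width peaks only, and other peak lists for the strength and GATA comparisons.

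The scripts were tested on simulated data. With 870 summits at random, the SKN-1 word passed an unadjusted 0.05 in 17 of 300 sets, and in 14 of 300 sets placed at random promoters, with a largest odds ratio of 1.50. Across 20 random sets, 0 of 620 list tests passed. These sets lay over the whole genome rather than at promoters, so they do not test the list calls for summits held to promoters. A list with 20 planted members returned all 20. A planted promoter share expected to give 70.5% gave 70.7%, and a planted replicate overlap expected to give 353.2 peaks gave 352.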

Results

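The peak lists describe where the tagged protein was found on chromatin of L2 larvae in 2 biological replicates of strain OP178. SKN-1, named by the strain and antibody labels, is a bZIP-related transcription factor of the oxidative stress response that also specifies early endoderm and mesoderm. PHA-4, named by the free-text description, is the forkhead factor that specifies the pharynx. In build ce11 the relaxed lists held 24771 peaks for replicate 1, 28630 for replicate 2 and 13302 for the pooled libraries. The optimal list held 872 peaks, 870 of them nuclear. Of the 872, 855 had the list's full width of 340 bp and 17 were narrower. The deposited signal in the optimal list ran from 43.2 to 2237, with a median of 54.2. This signal is the authors' own value for each peak, with no replicate error, and it ranks peaks within 1 list.

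The strongest nuclear peaks lay at genes of several kinds. The first, with a signal of 947, spanned chromosome II 10563429 to 10563699, directly upstream of cdc-48.1, which encodes a AAA ATPase that extracts ubiquitinated proteins. The next, with a signal of 651, spanned chromosome I 7595501 to 7595808 at the 5' end of wdr-23, which encodes a negative regulator of SKN-1 stability. The peak ranked 3 lay in an intron of skn-1 itself (chromosome IV 5657078 to 5657326, signal 610) and that ranked 4 in an intron of osgn-1 (chromosome IV 4215438 to 4215666, signal 503), named after its value was seen. Peaks ranked 5 to 8 lay between divergent gene pairs that each included a proteasome gene: rad-23 and rpn-12 (signal 371), hsp-110 and rpn-3 (324), aps-1 and rpt-2 (262), and ribo-1 and rpn-1 (255). With a shared promoter the gene of the pair cannot be told from the peak alone. The other promoters at the 20 strongest peaks were those of cbl-1, C02D5.4, msra-1, which encodes a methionine sulfoxide reductase, aqp-11, rpt-3, rpn-5 with scc-1, rpl-35, and nfyc-1 with rpt-4. Their signals ran from 196 at cbl-1 to 167 at nfyc-1 and rpt-4. Peaks ranked 11, 15 and 18 were intergenic, and that ranked 9 (signal 240) lay in a noncoding gene, F19G12.10, named after its value was seen.

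Genes of the proteasome, the complex that degrades ubiquitinated proteins, carried promoter peaks more completely than any other list tested. Of 31 proteasome genes, 28 had an optimal summit in the promoter, against 777 of all 19973 protein-coding genes (3.89%). The odds ratio was 239, with a 95% interval from 73.5 to 1231 (Fisher's exact test, adjusted p = 2.57e-35). The members with the strongest peaks were rpn-12, rpn-3, rpt-2 and rpn-1. The members without one were pbs-5, pbs-6 and rpn-10, named after their values were seen. Without the narrow peaks, an alternative chosen after seeing the data, 64.5% of members kept a peak, and the adjusted p by Fisher's exact test was 5.61e-20.

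Glutathione and detoxification genes formed the next group. In the list for glutathione and phase II detoxification 9 of 19 genes had a promoter summit (odds ratio 22.5, 95% interval 8.05 to 61.7; Fisher's exact test, adjusted p = 9.83e-08). This list is a hand-picked set, not every gene of these pathways. It includes gst-4, described below, and sdz-8 and nit-1, named here after their values were seen. Its share is thus not that of a neutral sample of such genes. The 9 genes with a summit included gst-1 (signal 157), gst-13 (155), gst-7 (122) and gcs-1 (120), which encodes the rate-limiting enzyme of glutathione synthesis. Of the 44 genes of the glutathione S-transferase family 13 had one (odds ratio 10.5, 95% interval 5.03 to 20.8; Fisher's exact test, adjusted p = 7.43e-08). The 2 lists share members. The peak at gst-4, a widely used reporter of SKN-1 activity, had a signal of 115.3, lay on chromosome IV 10141972 to 10142311, and fell in the promoters of gst-2 and dhs-12 too, the latter named after its value was seen, so that it counted for all 3. Members of the UDP-glucuronosyltransferase family (3 of 67) and the cytochrome P450 family (4 of 74) did not differ detectably from all genes (Fisher's exact test, adjusted p = 1 and 0.923). Of 17 antioxidant enzyme genes 2 had a summit, msra-1 (signal 186) and gpx-1 (135), a share that missed the threshold (Fisher's exact test, adjusted p = 0.395).

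Ribosomal protein genes were also higher than all genes, with 28 of 78 members (odds ratio 14.3, 95% interval 8.62 to 23.3; Fisher's exact test, adjusted p = 6.15e-19). Their strongest peaks were at rpl-35 (signal 170), rpl-20 (164), rpl-3 (147) and rpl-15 (124). Smaller groups passed as well. Cytosolic heat shock genes had 5 of 13, led by hsp-110 (324), hsp-90 (118), dnj-13 (60.1) and hsp-1 (51.9), with a Fisher's exact test adjusted p of 5.41e-04. SKN-1 regulators and cofactors had 5 of 16, led by wdr-23 (651), skn-1 (114.5), akt-2 (60.3) and ogt-1 (45.3), with a Fisher's exact test adjusted p of 0.00139. Genes of the endoplasmic reticulum unfolded protein response had 4 of 15, which were xbp-1 (87.8), crt-1 (60.1), atf-4 (44.5) and pdi-1 (44.1), with a Fisher's exact test adjusted p of 0.00975. These 3 calls rest on few peaks. With replicate 2's own strongest peaks in place of the optimal list, none of the 3 passed, with Fisher's exact test adjusted p of 0.0534, 0.0723 and 0.261 in the order given. The unfolded protein response did not pass with replicate 1's own strongest peaks either (13.3% of members; Fisher's exact test, adjusted p = 0.367).

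Lists of tissue identity held few or no peaks. Early endoderm and mesoderm genes (0 of 9, med-1 and med-2 among them), pharynx (0 of 21, pha-4 among them), intestine (0 of 24), hypodermis and cuticle (0 of 19), neurons (0 of 20), germ line (0 of 17) and Hox genes (0 of 6) had no member with a summit. With so few members these counts do not show a depletion: Fisher's exact test gave an adjusted p of 1 for each, and the upper 95% limit of the odds ratio was 4.75 for pharynx and 4.11 for intestine. Collagen genes of the col family had 0 of 156, fewer than all genes (upper 95% limit of the odds ratio 0.588; Fisher's exact test, adjusted p = 0.0199). That call was lost with replicate 2's own strongest peaks (Fisher's exact test, adjusted p = 0.136). The mitochondrial stress response had 2 of 9, hsp-60 (signal 87.0) and ubl-5 (44.99). Autophagy had 2 of 19, bec-1 (65.2) and lgg-2 (55.3), and innate immunity had 2 of 18, lys-8 (58.5) and zip-2 (49.9). Insulin signalling had 2 of 12, akt-2 and sgk-1 (44.2). Single members were nhr-49 of 21 lipid genes (43.8), unc-60 of 15 body wall muscle genes (43.5) and gpa-4 of 5 ASI neuron genes (46.0). The remaining families were nuclear hormone receptors (10 of 269), C-type lectins (6 of 237), ceh homeobox genes (1 of 63), histones (1 of 50), major sperm proteins (1 of 31) and hlh genes (1 of 25). None of these lists passed Fisher's exact test with adjustment, the smallest adjusted p being 0.156 for the mitochondrial stress response. Under other settings 3 of them did: the mitochondrial stress response with 3 of 9 members from replicate 2's own strongest peaks (Fisher's exact test, adjusted p = 0.0210) and with the longest promoter window tried (0.0306), and insulin signalling with 3 of 12 by nearest 5' end (0.0293). Nuclear hormone receptors passed against circular shifts of the summits, which are not held to promoters, with 10 members against a mean of 3.20 ± 1.72 (SD; permutation test, adjusted p = 0.008). With replicate 2's own strongest peaks the C-type lectins fell to 2 of 237 and the cytochrome P450 family to 1 of 74, without passing (Fisher's exact test, adjusted p = 0.0600 and 0.906). Lipid genes rose to 2 of 21 there (Fisher's exact test, adjusted p = 0.389). Insulin signalling fell to 1 of 12 with replicate 1's and with replicate 2's own strongest peaks (Fisher's exact test, adjusted p = 0.677 and 0.694).

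**Figure D1:**
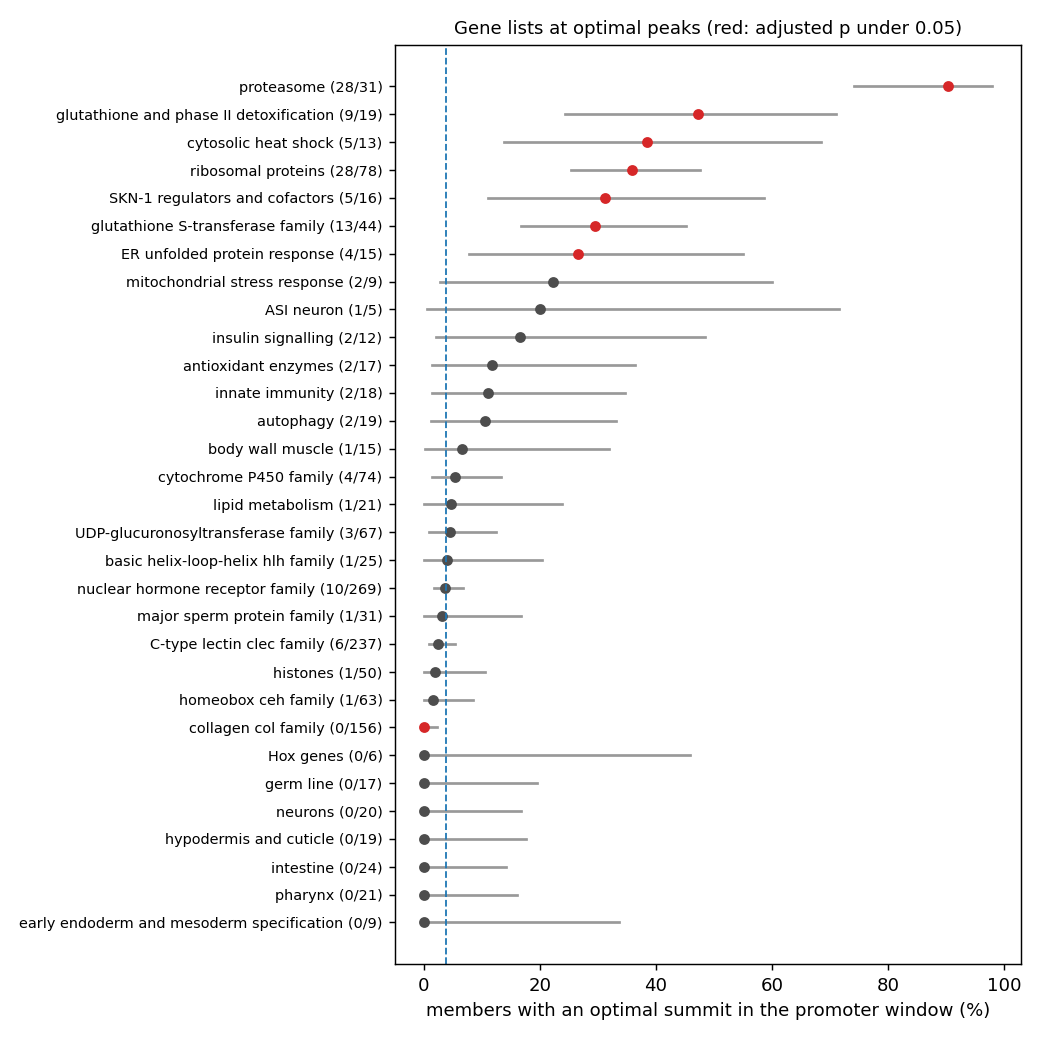
Share of each list's members with an optimal summit in the promoter, in percent on the horizontal axis. Points are the observed shares, bars their exact 95% intervals, the dashed line the 3.89% of all protein-coding genes, and red points the lists with an adjusted p under 0.05 by Fisher's exact test. The proteasome stands at 28 of 31 members, and collagens at 0 of 156 are the list that lies below the line with a red point.

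Since the labels name 2 proteins, the locus of each was examined. Within 20 kb of skn-1 (chromosome IV 5651039 to 5660384) lay 8 optimal summits, against a mean of 0.417 in 1000 random windows of the chromosome (permutation test, p = 0.006). That is a ratio of 19.2, which was 33.1 within 10 kb and 10.2 within 50 kb. Of these, 4 were inside the gene and 4 were on the higher-coordinate side, where the nearest was at the promoter of bec-1, and 2 had the SKN-1 word within 100 bp. In the relaxed lists 31 summits of replicate 1 and 33 of replicate 2 lay there, against random means of 12.1 and 14.03 (permutation test, p = 0.005 for each). Within 20 kb of pha-4 (chromosome V 20753052 to 20760317) lay 1 optimal summit, against a random mean of 0.376 (permutation test, p = 0.289), and it was intergenic. Per the labels the strain carries an integrated transgene of skn-1, whose extent and copy number are not given, so that peaks at skn-1 may come from the native locus or from the transgene.

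**Figure D2:**
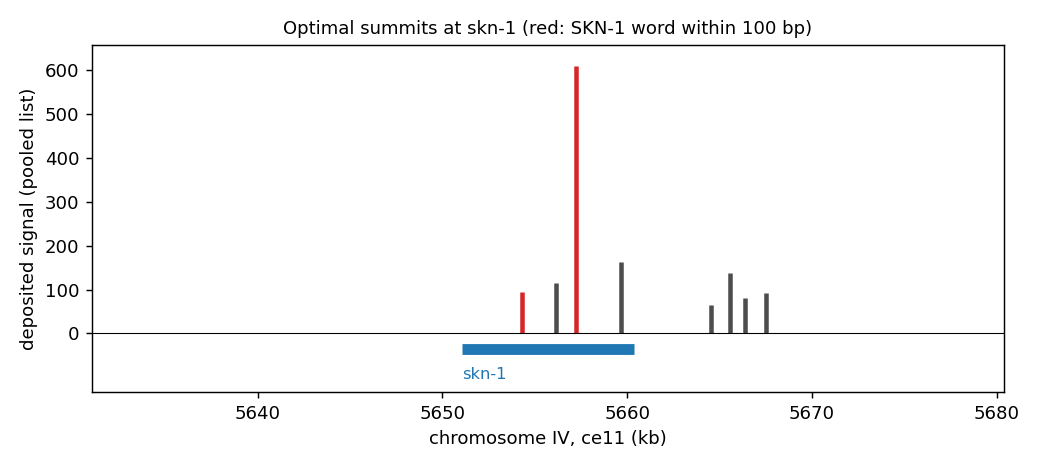
Optimal summits within 20 kb of skn-1, with position on chromosome IV in kb (ce11) on the horizontal axis and the deposited signal of the pooled list on the vertical axis. Each line is 1 of the 8 summits, red where the SKN-1 word lies within 100 bp, and the blue bar is the gene; the intronic peak of signal 610 is the highest.

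The sequence at summits was compared with that of flanking windows. The SKN-1 word WWTRTCAT (W is A or T, R is A or G) was present in 27.6% of 870 summit windows and 10.9% of 1718 flank windows (odds ratio 3.10, 95% interval 2.49 to 3.86; Fisher's exact test, adjusted p = 3.70e-25). The odds ratio was 4.95 at the stronger 435 peaks and 1.98 with the shorter word RTCAT. The PHA-4 word TRTTKRY was present in 59.7% and 47.7% (odds ratio 1.62, 95% interval 1.37 to 1.92; Fisher's exact test, adjusted p = 1.22e-08). Against dinucleotide shuffles the odds ratio was 1.81 for the PHA-4 word (95% interval 1.49 to 2.20; Fisher's exact test, p = 1.02e-09) and 3.14 for the SKN-1 word (95% interval 2.41 to 4.13; Fisher's exact test, p = 3.66e-19). Against promoters without a peak, the PHA-4 word no longer passed (odds ratio 1.26, 95% interval 0.991 to 1.59; Fisher's exact test, p = 0.0597), whereas the SKN-1 word did (odds ratio 3.67, 95% interval 2.58 to 5.27; Fisher's exact test, p = 3.93e-15). This background used only the 588 summits in promoters, with a matched window for each, so fewer windows were compared. The PHA-4 word was in 59.4% of those summit windows and 53.7% of the matched ones. A stricter PHA-4 word, TGTTTRC, was present in 13.7% of summit and 5.70% of flank windows. Its odds ratio of 2.62, with a 95% interval of 1.96 to 3.51, overlapped that of the SKN-1 word (Fisher's exact test, adjusted p = 3.56e-11). The GATA word TGATAA was present in 39.2% and 18.4% (odds ratio 2.86; Fisher's exact test, adjusted p = 1.33e-28) and GAGAGAGA in 7.01% and 0.990% (odds ratio 7.54; Fisher's exact test, adjusted p = 7.23e-16). The bZIP word TGASTCA (3.56% and 2.10%, odds ratio 1.73) and the E-box CACGTG (6.67% and 4.42%, odds ratio 1.54) were also more frequent at summits (Fisher's exact test, adjusted p = 0.0352 and 0.0217). Summit windows had a mean GC content of 38.6% ± 6.51 (SD, 870 windows) and flanks 35.99% ± 7.13 (SD, 1718 windows).

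The SKN-1 word was more frequent at stronger peaks. With the 870 peaks split by signal into 4 blocks, it was present at 98 of 218 in the strongest block, 65 of 218 and 35 of 217 in the next ones and 42 of 217 in the weakest. The odds ratio of strongest to weakest was 3.39 (95% interval 2.17 to 5.37; Fisher's exact test, adjusted p = 8.52e-08). The PHA-4 word stood at 64.2% in the strongest and 59.9% in the weakest block (odds ratio 1.20, 95% interval 0.800 to 1.80; Fisher's exact test, adjusted p = 0.607). The stricter PHA-4 word stood at 15.1% and 13.4% (odds ratio 1.16, 95% interval 0.651 to 2.06; Fisher's exact test, adjusted p = 0.795). The bZIP word TGASTCA was less frequent in the strongest block, 0.917% against 5.99% (Fisher's exact test, adjusted p = 0.0125).

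**Figure D3:**
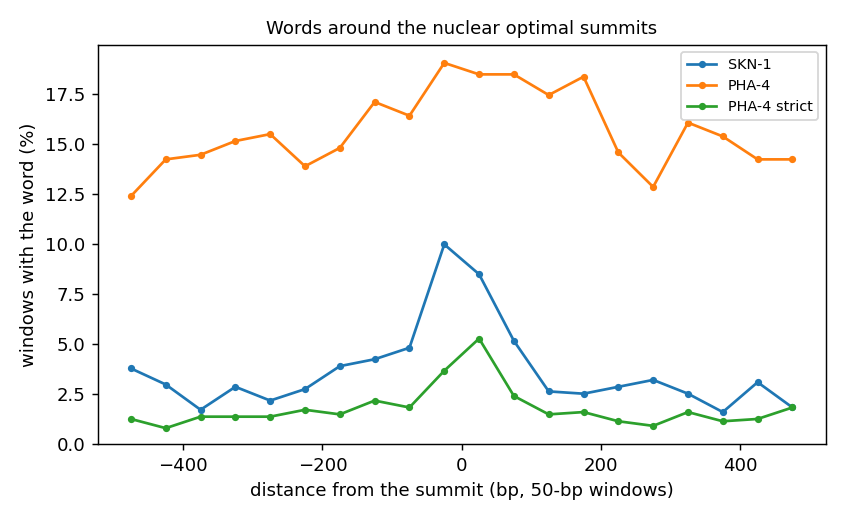
Share of windows of 50 bp with each word, in percent, by distance from the 870 nuclear summits in bp. Lines are the SKN-1 word, the PHA-4 word and the stricter PHA-4 word. The SKN-1 and stricter PHA-4 words peak at the summit. The PHA-4 word is common throughout and also highest there, with 19.1% from -50 to 0 bp against 12.4% from -500 to -450 bp.

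A search of all words of 7 bases, which assumes neither protein, tested 8192 words. Of these, 525 were more frequent at summits and 353 less frequent (Fisher's exact test, adjusted). The first was CTTATCA, whose reverse complement TGATAAG holds the GATA word, in 19.1% of summit and 2.79% of flank windows (Fisher's exact test, adjusted p = 2.83e-39). The next was ATGATGA, whose reverse complement TCATCAT holds the shorter SKN-1 word RTCAT. It was present in 22.2% and 4.42% (Fisher's exact test, adjusted p = 4.12e-38). CTGCGTC was present in 107 of 870 summit and 23 of 1718 flank windows (Fisher's exact test, adjusted p = 2.12e-28).

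Most optimal peaks lay at promoters. Of 870 summits 588 were in a promoter, 67.6% (95% interval 64.4 to 70.7) against 26.0% ± 1.45 (SD over 1000 placements) at random, a ratio of 2.60 (permutation test, adjusted p = 0.003). With a promoter of 500 bp upstream to 100 bp downstream the ratio was 4.09. Coding exons held 1.38% against 18.9% at random, and introns 7.36% against 27.5% (permutation test, adjusted p = 0.003 for each). The 3' UTR held 1.03% against 2.37% and other genes 1.49% against 3.38% (permutation test, adjusted p = 0.014 and 0.003), while the 5' UTR, 0.230% against 0.413%, did not differ detectably (permutation test, adjusted p = 0.723). Intergenic summits, 20.9% against 21.5%, did not differ detectably from random (permutation test, adjusted p = 0.759). With the longest promoter window tried they were fewer than random, 13.2% against 15.8% (permutation test, adjusted p = 0.042). The classes exclude each other and promoters are assigned first, so a high promoter share by itself lowers the share of every other class. Shares among summits outside promoters were not tested. The values for the other classes thus do not show whether summits outside promoters avoid or favour any of them. The strongest intergenic peak spanned chromosome X 12363038 to 12363377. Chromosome III carried 11.0 summits per Mb (95% interval 9.28 to 12.8), more than its share of length (exact binomial test, adjusted p = 0.0158). This call was lost with replicate 2's own strongest peaks (ratio to its share 1.17; exact binomial test, adjusted p = 0.138), where V fell below its share of length (ratio 0.824, against 0.887 in the optimal list; exact binomial test, adjusted p = 0.0467 and 0.262). X held 17.9% of summits and 17.7% of the length (exact binomial test, p = 0.824). Set against shares of protein-coding promoters instead, X and III each held 1.31 times their share (exact binomial test, adjusted p = 0.00107 for each) and V 0.740 times (exact binomial test, adjusted p = 3.24e-05).

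**Figure D4:**
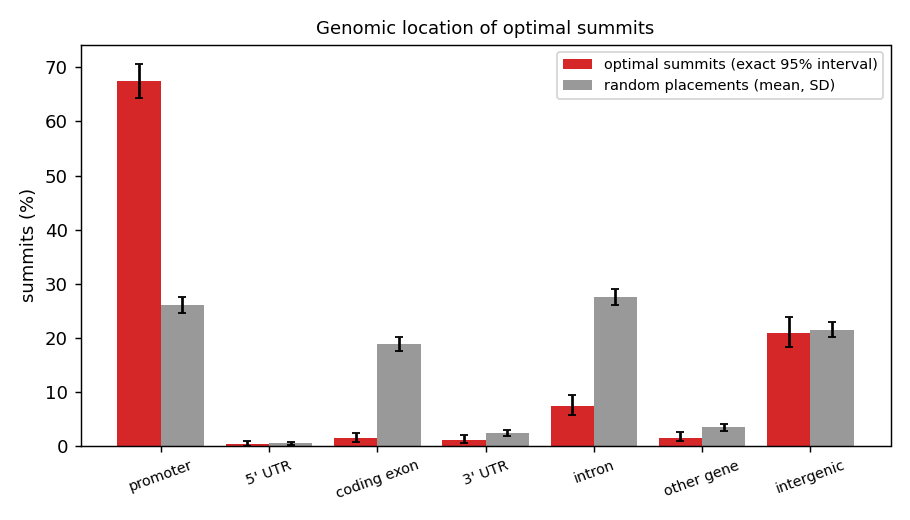
Genomic location of the 870 nuclear optimal summits, as percent of summits in each class. Red bars are observed shares with exact 95% intervals and grey bars the mean ± SD of 1000 random placements; promoters hold 67.6% against 26.0%.

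The replicates overlapped far more than chance and ranked peaks differently. Of the 872 strongest peaks of replicate 1, 423 (48.5%) were overlapped by one of the 872 strongest of replicate 2, against 4.94 ± 2.15 (SD) at random and at most 13 in 1000 placements (permutation test, p = 0.001, the smallest it can give). Of the 872 optimal peaks 869 overlapped a peak of replicate 1's relaxed list and 861 one of replicate 2's, and 858 (98.4%, 95% interval 97.3 to 99.1) overlapped both. The optimal list derives from these long relaxed lists, so a high overlap is largely built in and is no separate measure of replicate agreement. Among each replicate's 872 strongest peaks, 716 optimal peaks were matched in replicate 1 and 534 in replicate 2, with 299 in replicate 1 alone and 117 in replicate 2 alone (exact binomial test, p = 1.83e-19, chosen after seeing the data). This test treats peaks as independent. The median signal was 11.3 in replicate 1's relaxed list and 5.23 in replicate 2's, so a ranking by pooled signal can favour replicate 1's peaks in advance. Of replicate 2's 872 strongest peaks 23 were mitochondrial. The imbalance therefore does not show a difference in quality between the libraries. Across the 858 peaks matched in both, log2 signal gave Pearson's r = 0.52 and Spearman's rho = 0.30 (permutation test, p = 1e-05 for each, the smallest it can give). Without the 2 peaks farthest from the median r was 0.48, and over the 843 full-width peaks r was 0.38 and rho 0.27. Peaks are not independent replicates. The optimal peaks are also the 872 strongest of the pooled list. That choice on the signal of both replicates narrows the range and can lower the correlations.

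**Figure D5:**
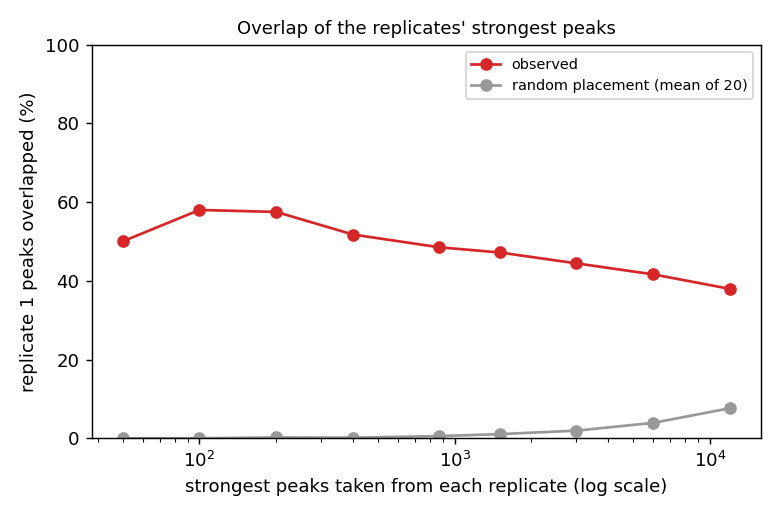
Percent of replicate 1's strongest peaks overlapped by the same number of replicate 2's strongest peaks, with the number taken from each on a log scale. Red points are observed and grey points random placements; observed overlap is 58% at 100 peaks and 37.9% at 12000, where random placement gives 7.64%.

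The builds were compared by number, width and signal at equal rank, without matching peaks. The optimal list held 879 peaks in ce10 and 872 in ce11, and the pooled list 13455 and 13302, with full widths of 336 and 340 bp. At equal rank the median ratio of pooled signal, ce10 over ce11, was 0.996.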

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

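The count of skn-1 flank peaks without optimal ones and by side, the tests that split the narrow peaks into nuclear and mitochondrial ones, and both searches behind the results in the last paragraph were chosen after the results were seen; the other tests here were fixed before.

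A cluster of optimal peaks lay at skn-1. If extra copies of the tagged region raise reads over the whole insertion, relaxed peaks in the 20 kb flanks outside the gene should be dense in both replicates. Replicate 1 had 19 and replicate 2 had 21, more than in 96.6% and 96.1% of 1000 random flank pairs on the chromosome, but these include peaks that overlap the optimal ones that raised the question. Without them the counts were 14 and 16, more than in 85.1% and 85.8% of pairs. The sides differed: the lower-coordinate side had 4 and 7 against random means of 4.65 and 5.59, and the higher-coordinate side 10 and 9 against 4.50 and 5.26, more than in 94.8% and 86.6% of windows. Extra copies thus stay open, since the extent of the insertion is not known. Binding of the tagged protein to its own gene stays open: 2 of 8 locus summits had the SKN-1 word against 27.6% of the others (Fisher's exact test, p = 1), too few summits to decide.

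The 10 strongest peaks were all narrow. The 17 narrow peaks ranked down to 85, with a median signal of 255 against 53.8 for full-width peaks. Exact repeats in the reference genome are argued against: 0 of the 17 narrow peaks (0%) held a word of 36 bases that recurs in it. Of full-width peaks 3.51% held one, and the groups could not be told apart (95% interval of the odds ratio 0 to 7.05). Copies that the reference does not show, of the transgene or of mitochondrial DNA, cannot be judged this way. A single library as the source was tested by overlap with both replicates' lists, which 88.2% of the narrow peaks had. Since 98.4% of all optimal peaks do, that overlap tells little. All 15 nuclear ones (100%, 95% interval 78.2 to 100) also overlapped one of the 872 strongest peaks of each replicate, against 47.0% of nuclear full-width peaks, which argues against a single library for them. For the 2 mitochondrial ones (0%) nothing can be told, because replicate 1's list holds no mitochondrial peak at all. How the caller sets peak width was not tested, and the design gives no biological explanation to test.

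The SKN-1 word was more frequent at summits. Base composition is argued against: the odds ratio was 3.14 against dinucleotide shuffles and 3.67 against promoters without a peak, and the lower of the lower 95% limits was 2.41. Whether the libraries hold PHA-4 rather than SKN-1 chromatin, as the free-text label reads, cannot be decided from the words. The SKN-1 word's odds ratio of 3.10 had a 95% interval apart from that of the PHA-4 word. The 2 words are not equally common, however, at 10.9% and 47.7% of flank windows. Against flank windows, comparison words reached like or higher odds ratios, 2.86 for GATA (95% interval 2.37 to 3.45) and 7.54 for GAGAGAGA (4.31 to 13.9). These words and the stricter PHA-4 word were not set against promoters without a peak. There the odds ratio was 3.67 for the SKN-1 word and 1.26 for the first PHA-4 word, TRTTKRY. The stricter PHA-4 word's interval, 1.96 to 3.51, is not apart from that of the SKN-1 word, so the words alone do not rule out PHA-4 at these sites. A biological reading, that these are SKN-1 sites, may be held as a hypothesis only, since the data of the control were not analysed here, and no second factor was.

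Mitochondrial and weaker peaks are outside the comparisons above. Replicate 2's relaxed list held 24 mitochondrial peaks and replicate 1's held 0, and 23 of the 24 were among replicate 2's 872 strongest. Whether mitochondrial peaks were removed from replicate 1's list is not given in the sources used here. If they were, the difference says nothing about the libraries. The strongest peak of the optimal list, with a signal of 2237, was mitochondrial. In the pooled peaks ranked 873 to 1744, just below the optimal list, the SKN-1 word was present in 17.2% of summit and 9.34% of flank windows (odds ratio 2.02, 95% interval 1.58 to 2.58; Fisher's exact test, adjusted p = 5.64e-08). In the weakest block, ranked 6977 to 13302, the odds ratio was 1.10 (95% interval 1.00 to 1.22). Flank windows of these blocks were cleared of the block's own summits only, so some may lie at optimal peaks.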

How the results depend on the processing

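Of 374 alternative values over 48 results, 348 were counted as unchanged. For values with a test, that meant keeping their side of the threshold. Values with no test were judged against the main one, and some counted as unchanged lay well away from it. The number of words more frequent at summits was 525 in the main search. It was 396 against dinucleotide shuffles, 355 with 6-base words and 434 with 8-base words. Of the 348, 37 crossed to the other side of no change, where neither value passed. The promoter ratio ran from 1.87 to 4.09, the SKN-1 odds ratio from 1.98 to 4.95, replicate overlap from 42.3% to 51.4%, and proteasome members with a peak from 64.5% to 96.8%. Optimal peaks in both relaxed lists fell to 96.0% with reciprocal 50% overlap and 91.3% with summits within 100 bp, as stricter rules must. Against promoter share the X ratio was 1.31, and against promoters without a peak the PHA-4 odds ratio was 1.26. Leaving out a replicate gave 5 to 7 passing lists. The 5 without replicate 1 include a gain, the mitochondrial stress response (33.3%), which also passed with the longest promoter (33.3%), as insulin signalling did with the nearest 5' end (25%). Leaving out a replicate gave 18.8% to 25% of SKN-1 regulators, 13.3% of unfolded protein response genes either way, which did not pass, 23.1% to 30.8% of heat shock genes and 0% to 0.641% of collagens, whose call was lost without replicate 1, as was that of chromosome III (ratio 1.17), while V fell below its share (0.824). With optimal peaks among the strongest of both replicates, chosen after seeing the data, 5 lists passed, and the unfolded protein response (13.3%), heat shock (15.4%), collagens (0%) and chromosome III (1.27) did not. With the stronger 435 peaks the unfolded protein response (13.3%) and collagens (0%) no longer passed. SKN-1 regulators (12.5%) did not pass with the promoter of 500 bp, nor collagens with the nearest 5' end (1.28%). Circular shifts (0%), with a mean of 1.65 members, could not have called fewer collagens. Intergenic summits were fewer than random with the longest promoter (ratio 0.836), where the high promoter share by itself lowers the other classes. Nuclear hormone receptors (3.72%) lay below all genes but above circular shifts, which are not held to promoters. Other causes were not tested. Depth is unknown, so its limits could not be assessed.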

Other observations

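These values were all computed after the main results were seen. The SKN-1 word was counted at peaks of the passing lists. All 9 peaks at glutathione and phase II genes had it, as did 9 of 12 at the glutathione S-transferase family and 14 of 29 at proteasome genes, against 2 of 27 at ribosomal protein genes. Compared with the other optimal peaks, the word was more frequent at glutathione (Fisher's exact test, adjusted p = 5.80e-05), glutathione S-transferase (0.00279) and proteasome peaks (0.0319), and less frequent at ribosomal protein peaks (0.0319). Proteasome and ribosomal protein peaks differed directly (odds ratio 11.2, 95% interval 2.12 to 114.6; Fisher's exact test, p = 9.13e-04), and no peak belonged to both. Peak strength was not held equal in any of these comparisons. The median signal was 105.1 at proteasome and 59.7 at ribosomal protein peaks. In the strongest block of all peaks 98 of 218 had the word, a share close to that of proteasome peaks. The proteasome call and the direct difference thus cannot be told apart from peak strength. Peaks at heat shock (0 of 5), unfolded protein response (0 of 4) and SKN-1 regulator genes (1 of 5) did not differ detectably from the others (Fisher's exact test, adjusted p = 0.462, 0.677 and 1).

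The SKN-1 and GATA words can share bases, so forms of each were counted apart. The GATA word not preceded by A (BTGATAA, B being C, G or T) was present in 32.3% of summit and 14.1% of flank windows (odds ratio 2.89, 95% interval 2.37 to 3.54; Fisher's exact test, adjusted p = 8.64e-26). The SKN-1 word with G at base 4 (WWTGTCAT) was present in 17.8% and 5.12% (odds ratio 4.01, 95% interval 3.02 to 5.35; Fisher's exact test, adjusted p = 7.89e-24), and that with A there (WWTATCAT) in 107 of 870 and 106 of 1718 (odds ratio 2.13, 95% interval 1.59 to 2.86; Fisher's exact test, adjusted p = 2.03e-07). At summits the GATA form and the G form did not occur together more than apart (odds ratio 1.19, 95% interval 0.809 to 1.74; Fisher's exact test, adjusted p = 0.345). Of summits with CTGCGTC 17.8% had the GATA form, against 34.3% of the others (odds ratio 0.413, 95% interval 0.232 to 0.702; Fisher's exact test, adjusted p = 0.00168).

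Optimal summits also lay near the 5' ends of small RNA genes, in windows set as for promoters. The number was 26 for snoRNA genes against a mean of 3.95 ± 1.94 (SD) over 1000 placements that kept the number of summits at protein-coding promoters (permutation test, adjusted p = 0.004), and 19 of the 26 were at such promoters as well. It was 18 for tRNA genes against 5.72 ± 2.35 and 7 for snRNA genes against 1.26 ± 1.14 (permutation test, adjusted p = 0.004 for each), and 8 for miRNA genes against 2.52 ± 1.54 (permutation test, adjusted p = 0.01). Of these, 7 of the 18, 5 of the 7 and 4 of the 8 were at protein-coding promoters as well. The ncRNA class had 113 against 68.0 ± 7.96 (permutation test, adjusted p = 0.004), 69 of them at such promoters. The number was 30 for piRNA genes against 35.2 ± 5.37, which did not differ detectably (permutation test, adjusted p = 0.38). Neither did lincRNA genes, 5 against 2.15 ± 1.42, or pseudogenes, 12 against 17.6 ± 4.15 (permutation test, adjusted p = 0.171 and 0.245). Placements outside promoters did not avoid exons or introns, where few optimal summits lay, so location alone could raise the numbers observed over random.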
